A study of Homo sapiens with 6 samples.

How the data were processed

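Total RNA from 3 wild-type and 3 DBC1 knockout cultures of SW480 cells was labelled with biotin and hybridised to Affymetrix expression arrays, 1 array per culture, per the labels' protocols. The cells had been grown in DMEM with fetal bovine serum, and RNA was extracted with the RNeasy kit, per the same protocols. The labels call the 3 samples of each genotype independent biological replicates, so p-values measure the spread between such replicates. Whether the knockout replicates came from 1 clone or several was not given in the sources used here, and what separates 2 cell populations in culture is then not separated from the knockout.

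The values are log2 expression for 33297 probe sets on 6 arrays, used as the authors deposited them. The submitters' processing notes name GCOS, Affymetrix's scanner software, and RMA, which corrects background, quantile-normalizes across arrays and combines the probes of a set, with no version of either. RMA gives no detection call, and it holds dim transcripts near a background level, so folds of genes that reach that level are understated. Array medians ran from 7.59 to 7.67 and values from 2.24 to 14.5. No scanner files were used here. All 6 value columns were matched to samples by their labels, and no 2 arrays held the same values (11 to 28 probe sets were identical in any pair). The number of arrays limits the precision.

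Probe sets were named through the platform's annotation table. Of the 33297, 19460 had 1 gene symbol, 1754 had several and 12083 were not listed there. Symbols were compared with a RefSeq gene table of assembly GRCh38.p14 by Entrez ID, where 19429 of the 19460 matched and 0 symbols changed. That table was used only for names, chromosomes and the order of genes, and no coordinates are given, because the build behind the array's annotation was not given in the sources used here. For the 769 genes with more than 1 probe set, the one with the highest mean over all arrays was used, which left 18417 genes. Probe sets with several symbols or none stayed out of the gene results. No filter on dim genes was applied.

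Knockout was compared with wild type in R 4.3.3 with limma 3.58.1 (lmFit and eBayes, no covariates, two-sided), with the Benjamini-Hochberg adjustment over the 18417 genes and a threshold of 0.05 on the adjusted p. A change of at least 2-fold was counted separately. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over the 32 lists, and again with the correlation estimated from the data, with fry and with camera on ranks. The lists, the rule for named genes, the test and all alternatives except those described as added were fixed before the data were examined. Named genes were, first, CCAR2, CCAR1, SIRT1, CTNNB1, PROX1, AXIN2, LGR5, MYC, CCND1, LEF1 and TCF7. To these were added the 12 largest rises and the 12 largest falls among genes past the threshold whose groups did not overlap, and up to 4 members of each list past the threshold with the lowest p. The lists were drawn up from textbook knowledge, and 3 of them hold markers of fibroblasts, immune cells and endothelial cells.

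The alternatives were a second quantile normalization, centring each array on its median, a common 75th percentile, leaving out genes below the 40th percentile of probe sets, the mean or the most variable probe set of a gene, a trended robust prior, array weights, 16 added on the linear scale, the replicate number as a block, each replicate left out in turn, and every probe set tested on its own. A scan for neighbouring genes that moved together was added after the data were seen. It took the median difference of 21 consecutive genes above the dim filter along each chromosome (13584 genes) and compared it with the largest median in each of 9999 shuffled gene orders.

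The steps were tested on simulated data. With 200 of 18417 genes changed between 3 and 3 arrays, limma recovered 32% of changes of 0.3 on the log2 scale, 88% of 0.6, 98% of 1 and 100% of 2, with 8 false calls. In the real comparison 39.3% of genes passed, and the adjustment depends on that share, so the recovery of small changes there may differ. In the same simulated comparison camera called the 1 list that had been shifted and 0 of the others. Noise was drawn there independently for each gene, so false calls from correlated genes were not tested. With the real arrays split in other ways than by genotype, camera called 2 to 5 lists. Each such split mixes the genotypes unequally and keeps part of their difference, so these counts are not a rate of false calls. Over 13584 genes in shuffled order, the scan found the 1 planted run and 0 others.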

Results

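Gene expression was measured in SW480 cells, an established human colorectal cancer line, in the wild-type state and after knockout of DBC1. The gene, whose official symbol is CCAR2, encodes a nuclear protein known as an inhibitor of the deacetylase SIRT1. It had been disrupted with TALENs, engineered nucleases that cut DNA at a chosen site. The series asked how loss of DBC1 alters expression across the genome, and it held 3 wild-type and 3 knockout arrays, labelled as independent biological replicates. How many knockout clones these came from was not given in the sources used here. The array medians lay between 7.59 and 7.67 on the log2 scale. Across probe sets, arrays of the same genotype correlated with r from 0.996 to 0.997, and arrays of different genotype with r from 0.988 to 0.989. The number of arrays limits the precision of every value. Differences are knockout minus wild type on the log2 scale, followed by the standard error from limma, with n = 3 per genotype throughout, and adjusted p-values are limma's with the Benjamini-Hochberg adjustment over 18417 genes.

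CCAR2, the targeted gene, was lower in all 3 knockout arrays. Its level was 10.02 ± 0.0804 in wild-type and 8.79 ± 0.105 in knockout cells (mean ± SD, n = 3 each), a 2.34-fold fall (log2 difference -1.22 ± 0.0691, adjusted p = 2.61e-06 by limma). A nuclease lesion acts on the reading frame and need not remove the transcript, and the array has 1 probe set with the CCAR2 symbol alone, whose position relative to the lesion was not given in the sources used here. CCAR2 lies on chromosome 8 in a region where other genes were lower too. Of its 40 nearest measured genes, 27 fell and 1 rose, with a median difference of -0.29, and 1 of them fell as much as CCAR2. In the stretch from PINX1 to SORBS3, which ends shortly before CCAR2, 5 of 42 genes fell as much.

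Among genes tied to DBC1 and to β-catenin, the paralog CCAR1 rose 1.44-fold (0.53 ± 0.0561, adjusted p = 0.000123) and SIRT1, whose product DBC1 is known to inhibit, rose 1.56-fold (0.64 ± 0.0747, adjusted p = 0.000214). PROX1, a homeobox transcription factor active in colorectal tumours, fell 2.86-fold (-1.51 ± 0.0796, adjusted p = 1.71e-06). LGR5, the R-spondin receptor that marks intestinal stem cells, fell 10.3-fold, from 9.19 ± 0.0598 to 5.82 ± 0.302 (mean ± SD, n = 3 each; adjusted p = 2.75e-07). MYC fell by a smaller amount (-0.29 ± 0.0485, adjusted p = 0.00144), while AXIN2 (0.24 ± 0.0471, adjusted p = 0.00401) and CCND1 (0.21 ± 0.0497, adjusted p = 0.00838) rose. CTNNB1, which encodes β-catenin itself, differed by -0.02 ± 0.0475 (adjusted p = 0.744) and LEF1 by 0.04 ± 0.0591 (adjusted p = 0.597), both within the spread between replicates. TCF7 had no probe set that carries its symbol alone and is not analysed here.

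The steepest differences among the measured genes were falls. CCL20, a chemokine that attracts lymphocytes and dendritic cells, went from 11.55 ± 0.0879 to 5.73 ± 0.192 (mean ± SD, n = 3 each), 56.8-fold lower (adjusted p = 2.51e-09). SEMA3A, a secreted guidance factor, was 36.5-fold lower (-5.19 ± 0.0576), and the chemokine CCL2 was 23.7-fold lower (-4.57 ± 0.0849). DKK1, a secreted inhibitor of Wnt signalling, fell 27.6-fold (-4.79 ± 0.0499), and GPX2, the gastrointestinal glutathione peroxidase, fell 27.8-fold (-4.8 ± 0.0630). The other members of the 12 largest falls were CA6, a secreted carbonic anhydrase (-4.82 ± 0.0654), CNTN1, a neural adhesion molecule (-4.82 ± 0.104), SERPINI1, a serine protease inhibitor (-4.46 ± 0.0595), PHYHIPL (-4.32 ± 0.111), and KLRC2 (-4.96 ± 0.117), DEFA5 (-4.84 ± 0.0936) and AKR1C3 (-4.19 ± 0.144). The last 3 have close paralogs whose transcripts the probes could share, so their values are less certain. CCL20 stood at 5.73 in knockout cells, near the 25th percentile of those arrays (5.74 to 5.77), and no detection calls were used here, so a transcript at such a level cannot be told from one that is absent.

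**Figure D1:**
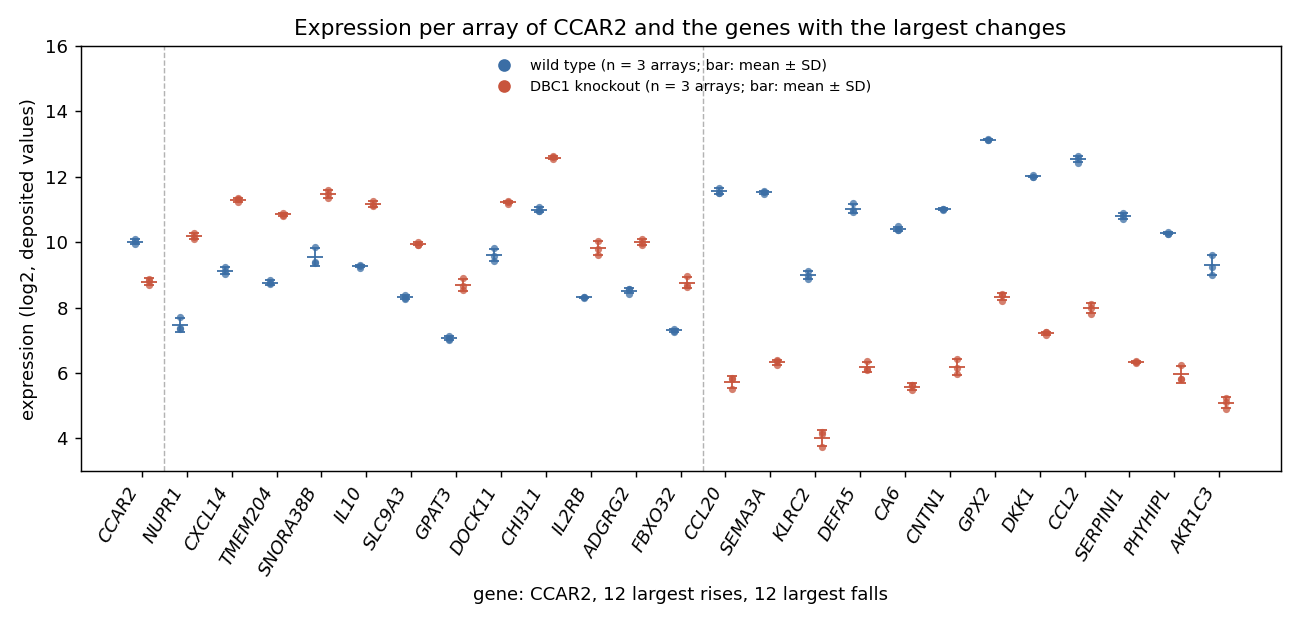
Log2 expression (vertical axis) of CCAR2, the 12 genes with the largest rises and the 12 with the largest falls, with 1 point for each of the 3 wild-type and 3 knockout arrays and bars for the mean ± SD. The groups do not overlap for any gene shown, from CCL20 (-5.83) to NUPR1 (2.71).

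Rises were smaller. NUPR1, a stress-induced transcriptional regulator, rose 6.56-fold, from 7.47 ± 0.202 to 10.18 ± 0.0921 (mean ± SD, n = 3 each; adjusted p = 1.9e-07). The chemokine CXCL14 rose 4.48-fold (2.16 ± 0.0694) and the membrane protein gene TMEM204 rose 4.23-fold (2.08 ± 0.0551). The cytokine IL10 rose 3.73-fold (1.9 ± 0.0579), the sodium-hydrogen exchanger SLC9A3 3.11-fold (1.64 ± 0.0549) and CHI3L1, a secreted chitinase-like protein, 3.03-fold (1.6 ± 0.0577). GPAT3 (1.63 ± 0.0876), DOCK11 (1.61 ± 0.0895), IL2RB (1.5 ± 0.0965), ADGRG2 (1.48 ± 0.0684) and FBXO32 (1.47 ± 0.0805) also rose, as did SNORA38B (1.93 ± 0.126), a small nucleolar RNA whose probes may also read its host transcript.

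Over all genes, 7229 of 18417 (39.3%) passed adjusted p under 0.05 by limma, 3912 of them higher and 3317 lower in knockout cells (54.1% higher). With each array centred on its own median, the split was 5055 higher and 2737 lower (64.9% higher). Of the 458 genes that also differed at least 2-fold, 66 were higher and 392 lower (85.6% lower). At 4-fold or more, 3 were higher and 116 lower, and at 8-fold or more 0 were higher and 47 lower. The 3 knockout values lay wholly outside the 3 wild-type values for 9420 genes (51.1%), where chance gives 10%.

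Of 32 gene lists, 12 passed limma's camera test with its preset correlation between genes, 5 towards higher and 7 towards lower expression. With the correlation estimated from these arrays none of the 32 passed, although 5 lay at an unadjusted p under 0.05. That loss of calls is not due to correlation alone. For the YAP and TEAD target list the estimate was -8.57e-05, below the preset 0.01, yet camera's unadjusted p went from 0.00221 to 0.0285. With an estimated correlation camera also allows for the small number of arrays, which makes an adjusted call hard to reach. The rotation test fry, which asks only whether a list's own genes moved one way on balance, called 24, the 12 that passed camera included. Counts adjusted over the list alone equal those given unless stated. Members named for moving against their list were chosen after their values were seen.

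**Figure D2:**
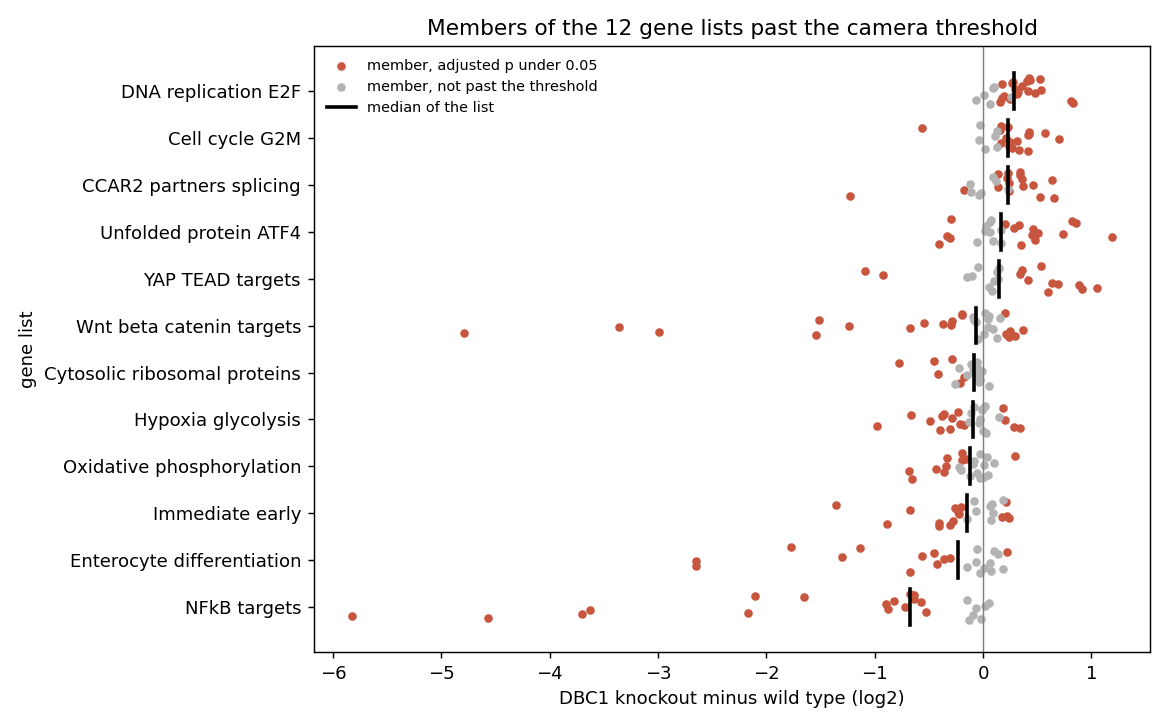
Log2 difference, knockout minus wild type (horizontal axis), of each measured member of the 12 gene lists that passed camera (vertical axis), with 1 point per gene, coloured where the gene passed adjusted p under 0.05, and a bar at each list's median. The NF-κB list sits lowest, with a median of -0.68, and the DNA replication list highest, with a median of 0.29.

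Genes driven by NF-κB, the transcription factor of inflammatory signalling, fell. Of 23 measured members, 16 fell, 0 rose and 7 did not pass, with a median difference of -0.68 (camera adjusted p = 2.23e-11; adjusted p = 0.23 with an estimated correlation). Besides CCL20 and CCL2, the neutrophil chemokine CXCL8 fell 12.3-fold (-3.62 ± 0.0741) and TNFAIP3, a feedback inhibitor of the pathway, fell 4.29-fold (-2.1 ± 0.0522).

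Cell cycle genes moved the opposite way, by smaller amounts. Of 26 DNA replication genes, which E2F factors are known to drive, 20 rose and 0 fell, while 6 did not pass, and 21 rose when adjusted over the list alone. The median difference was 0.29 (camera adjusted p = 2.75e-06; adjusted p = 0.23 with an estimated correlation). Cyclin gene CCNE2 (0.83 ± 0.0600) and the origin licensing factor CDC6 (0.82 ± 0.0777) rose most clearly, followed by TYMS, the thymidylate synthase (0.53 ± 0.0533), and the helicase subunit MCM5 (0.54 ± 0.0613). Of 24 mitotic genes, 17 rose, 1 fell and 6 did not pass, with 18 rising when adjusted over the list alone (median 0.23; camera adjusted p = 0.00116; adjusted p = 0.435 with an estimated correlation). The mitotic kinesins KIF23 (0.57 ± 0.0716) and CENPE (0.70 ± 0.0981) and the spindle gene ASPM (0.42 ± 0.0579) rose, whereas PTTG1, which encodes securin, fell (-0.57 ± 0.0531).

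Markers of differentiated enterocytes fell more often than they rose. Of 22 measured, 11 fell, 1 rose and 10 did not pass (median -0.23; camera adjusted p = 0.00116; adjusted p = 0.23 with an estimated correlation). The brush border peptidase DPP4 fell 6.26-fold (-2.65 ± 0.0862), the intestinal cadherin CDH17 6.27-fold (-2.65 ± 0.119), the microvillus protein VIL1 3.42-fold (-1.77 ± 0.0513) and the glucose transporter SLC5A1 2.2-fold (-1.14 ± 0.0523), while MS4A12 rose (0.22 ± 0.0638). The MS4A12 call was lost without wild-type replicate 1 or 2 or knockout replicate 1 or 2 (adjusted p = 0.0619 to 0.0800), and 2 rose without knockout replicate 3. Markers of secretory cells included steep falls of the Paneth cell defensins DEFA5 (-4.84) and DEFA6 (-2.47 ± 0.0928), of the goblet cell peptide TFF3 (-3.23 ± 0.133) and of lysozyme, LYZ (-1.21 ± 0.0625). Over that list 4 fell, 3 rose and 11 did not pass, its median of 0.08 and mean of -0.57 differed in sign, and camera did not call it (adjusted p = 0.578; adjusted p = 0.806 with an estimated correlation). Its rises numbered 1 without wild-type replicate 1, 2 or 3 or knockout replicate 3. Of 15 stem cell markers 2 rose, 5 fell and 8 did not pass, with LGR5 and PROM1 (-0.61 ± 0.120) lower and LRIG1 (0.26 ± 0.0458) and EPHB3 (0.25 ± 0.0552) higher (camera adjusted p = 0.168; adjusted p = 0.435 with an estimated correlation). PROM1 lay below the level of the dim filter (6.86) already in wild-type cells (6.24).

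Wnt and β-catenin target genes went both ways. Of 31 measured, 13 fell, 6 rose and 12 did not pass, with a median of -0.07 and a mean of -0.52 (camera adjusted p = 0.0138; adjusted p = 0.496 with an estimated correlation). The lowest p-values belonged to falls of DKK1 and of DKK4, another secreted Wnt inhibitor (7.97-fold, -3.0 ± 0.0599), of LGR5 and of the growth factor BMP4 (2.91-fold, -1.54 ± 0.0654). On ranks in place of values the list's adjusted p was 0.113.

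Stress and growth pathways moved in both directions. Of 25 genes of the unfolded protein response and ATF4, 12 rose, 4 fell and 9 did not pass, and 14 rose when adjusted over the list alone (median 0.17; camera adjusted p = 0.0101; adjusted p = 0.23 with an estimated correlation). DDIT3, which encodes the stress factor CHOP, rose 2.29-fold (1.2 ± 0.0813), with rises of TRIB3 (0.83 ± 0.0548), the cystine transporter SLC7A11 (0.86 ± 0.0641) and the chaperone DNAJC3 (0.74 ± 0.0575). The falls were ATF3 (-0.40 ± 0.0603), DDIT4 (-0.33 ± 0.0647), XBP1 (-0.29 ± 0.0628), the splicing-activated regulator of the response, and CTH (-0.31 ± 0.0851), the last with an adjusted p of 0.0533 to 0.0646 without wild-type replicate 2 or 3 or knockout replicate 1. Of 21 YAP and TEAD target genes, 10 rose, 2 fell and 9 did not pass, against 11 and 3 adjusted over the list alone (median 0.15; camera adjusted p = 0.0101; adjusted p = 0.23 with an estimated correlation). ANKRD1 (1.05 ± 0.0475), AMOTL2 (0.92 ± 0.0454) and the receptor kinase AXL (0.69 ± 0.0490) rose, and NT5E, an ectonucleotidase (-1.09 ± 0.0671), and GADD45A fell. AMOTL2 lies in a stretch of chromosome 3 where neighbouring genes were higher. Of 23 immediate early genes, 11 fell, 4 rose and 8 did not pass, with 5 rising when adjusted over the list alone (median -0.15; camera adjusted p = 0.0403; adjusted p = 0.504 with an estimated correlation). PHLDA1 (-1.36 ± 0.0610), the phosphatase genes DUSP4 (-0.89 ± 0.0563) and DUSP5 (-0.40 ± 0.0551), and JUN (-0.68 ± 0.0530) fell, whereas FOS (0.22 ± 0.0488), ETV4 (0.24 ± 0.0532), ETV5 (0.17 ± 0.0501) and SPRED2 (0.22 ± 0.0720) rose. The calls of ETV5 and SPRED2 were lost without wild-type replicate 1, 2 or 3 or knockout replicate 2 or 3 (adjusted p = 0.0562 to 0.106), which left 2 rises. That list no longer passed without wild-type replicate 3 (adjusted p = 0.0705), without knockout replicate 1 (0.0918), without dim genes (0.0620), with array weights (0.0756) or on ranks (0.113).

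The 3 lists of energy metabolism and ribosomal proteins pointed lower by camera, with small medians and many members that did not pass. Of 23 respiratory chain genes, 9 fell, 1 rose and 13 did not pass (median -0.12; camera adjusted p = 0.0144; adjusted p = 0.427 with an estimated correlation), with COX6C (-0.69 ± 0.0947) and ATP5F1A (-0.65 ± 0.0801) among the falls and SDHD the rise (0.29 ± 0.0462). Of 26 hypoxia and glycolysis genes, 11 fell, 4 rose and 11 did not pass (median -0.09; camera adjusted p = 0.0238; adjusted p = 0.435 with an estimated correlation), led by the oxygen sensor EGLN3 (-0.98 ± 0.0486) and the glycolytic regulator PFKFB3 (-0.67 ± 0.0532), but the list's adjusted p was 0.0627 without wild-type replicate 3. Its rises were EGLN1 (0.28 ± 0.0519), BNIP3 (0.34 ± 0.0764), KDM3A (0.20 ± 0.0489) and SLC2A3 (0.19 ± 0.0492), the last with an adjusted p of 0.0539 without knockout replicate 3. Of 23 ribosomal protein genes, 6 fell, 0 rose and 17 did not pass (median -0.08; camera adjusted p = 0.00381; adjusted p = 0.435 with an estimated correlation), with RPS24 (-0.78 ± 0.0609) and RPS6 (-0.45 ± 0.0488) lowest in p, the latter within a stretch of chromosome 9 where neighbouring genes were lower.

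Of 23 genes for DBC1 partners and splicing factors, 14 rose, 2 fell and 7 did not pass, with 15 rising when adjusted over the list alone (median 0.23; camera adjusted p = 0.0138; adjusted p = 0.435 with an estimated correlation). The falls were CCAR2 itself and HDAC3 (-0.18 ± 0.0518). The adjusted p of HDAC3 reached 0.0844 with 1 array left out (wild-type replicate 1) and was at or above 0.05 without any other array but wild-type replicate 2 (0.0849 with each array centred on its median). BRCA1, the DNA repair gene, rose (0.66 ± 0.0647). Of 16 sirtuin and NAD genes, SIRT1 alone rose, 5 fell and 10 did not pass, with SIRT2 (-0.38 ± 0.0616) and SIRT6 (-0.29 ± 0.0528) among the falls (camera adjusted p = 0.472; adjusted p = 0.575 with an estimated correlation). Without wild-type replicate 2 or knockout replicate 1 there were 3 falls, and with each array centred on its median 5 genes rose and 3 fell.

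The remaining lists did not pass camera. Of 22 epithelial junction genes 7 fell and 3 rose (adjusted p = 0.114; adjusted p = 0.427 with an estimated correlation), with CLDN1, a tight junction claudin, 3.95-fold lower (-1.98 ± 0.0596) and the desmosomal cadherin DSC2 2.53-fold lower (-1.34 ± 0.0623). Without wild-type replicate 2 the list had 1 rise. Of 26 mesenchymal genes 8 fell and 4 rose (adjusted p = 0.147; adjusted p = 0.435 with an estimated correlation), with falls of the proteoglycan LUM (-3.49 ± 0.0723), the cadherin CDH11 (-1.66 ± 0.0675) and the transcription factor SNAI2 (-1.24 ± 0.0806) and a rise of the matrix protease MMP2 (0.74 ± 0.0549). TGF-β and SMAD genes split into 5 rises and 7 falls of 20, 6 and 7 adjusted over the list alone (adjusted p = 0.472; adjusted p = 0.792 with an estimated correlation), with ID1 (-1.64 ± 0.0718) lower and LTBP2 (1.16 ± 0.0529) higher.

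Interferon response genes showed 12 rises and 7 falls of 29, 13 and 7 adjusted over the list alone (adjusted p = 0.446; adjusted p = 0.752 with an estimated correlation). The RNA sensor RIGI rose 2.52-fold (1.33 ± 0.0710), and it lies in a stretch of chromosome 9 where neighbouring genes were higher, while SAMD9 fell (-0.92 ± 0.0680). Of 12 antigen presentation genes 5 fell and 3 rose, with 4 rises adjusted over the list alone (adjusted p = 0.206; adjusted p = 0.435 with an estimated correlation), with the class II genes HLA-DPA1 (-2.01 ± 0.0907) and HLA-DPB1 (-1.08 ± 0.0762) lower. The list holds 20 genes, and the others had no probe set with their symbol alone. Class II probe sets with several symbols were thus not counted, and those with the lowest p all fell. With every probe set tested on its own, 8178193 (HLA-DRA and HLA-DQA1) differed by -2.37 and 8178811 (HLA-DRB genes and HLA-DQB1) by -2.43. HLA genes are similar in sequence, so probes may share their transcripts.

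Of 18 cholesterol synthesis genes 9 rose and 2 fell, 9 and 3 adjusted over the list alone (adjusted p = 0.125; adjusted p = 0.472 with an estimated correlation), INSIG1 (0.44 ± 0.0487) and IDI1 (0.40 ± 0.0525) among the rises. Without wild-type replicate 3 or knockout replicate 1 or 2 there was 1 fall. Of 18 fatty acid genes 10 rose and 5 fell, 11 and 5 adjusted over the list alone, and the median of 0.19 and mean of -0.06 differed in sign (adjusted p = 0.672; adjusted p = 0.87 with an estimated correlation). The adipogenic receptor PPARG fell 2.72-fold (-1.44 ± 0.0496) and the lipid droplet protein PLIN2 fell 2.3-fold (-1.2 ± 0.0547), the latter within the same lower stretch of chromosome 9 as RPS6. NRF2 targets gave 6 rises and 4 falls of 19, 6 and 6 adjusted over the list alone (adjusted p = 0.472; adjusted p = 0.792 with an estimated correlation), with AKR1C3 and the transporter ABCC2 (-1.41 ± 0.0720) lower and SLC7A11 higher.

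Of 26 p53 targets 6 rose and 7 fell (adjusted p = 0.609; adjusted p = 0.792 with an estimated correlation), the falls including the death receptor gene TNFRSF10B (-0.63 ± 0.0467) on chromosome 8, GADD45A (-0.93 ± 0.0757) and the cell cycle inhibitor CDKN1A (-0.47 ± 0.0632). Of 20 apoptosis genes 2 rose and 3 fell, 1 and 3 adjusted over the list alone, with BCL2L11, BOK and BID lower (-0.37, -0.36 and -0.34), a median of 0.06 and a mean of -0.01 (adjusted p = 0.895; adjusted p = 0.913 with an estimated correlation). Of the rises, BAD lost its call without wild-type replicate 2 or 3 or knockout replicate 1, 2 or 3 (adjusted p = 0.0556 to 0.0814). CASP9 lost its call without wild-type replicate 1 or 2 or knockout replicate 1 or 3 (0.0801 to 0.142). Histone genes rose in 5 of 15 cases with 0 falls (adjusted p = 0.52; adjusted p = 0.792 with an estimated correlation), H4C8 with the lowest p (0.44 ± 0.0689). That count was 1 without wild-type replicate 1 or knockout replicate 3, 2 without wild-type replicate 3, and 3, with 1 fall, without wild-type replicate 2. H2BC11, H2AX and H2AZ1 lost their calls without knockout replicate 3 (adjusted p = 0.0625, 0.0759 and 0.132). Heat shock genes gave 3 rises and 2 falls of 14, with a median of 0.02 where camera pointed lower (adjusted p = 0.976; adjusted p = 0.986 with an estimated correlation). The second fall, HSPE1, was lost without wild-type replicate 1 (adjusted p = 0.0684) or 3 (0.0521), without knockout replicate 2 (0.0605) or with each array centred on its median (0.0667). The chaperone HSPA4L fell 2.0-fold (-1.0 ± 0.0565), while DNAJA1 (0.61 ± 0.0557), in the higher stretch of chromosome 9, and CRYAB (0.58 ± 0.0599) rose. Ribosome biogenesis genes gave 4 rises and 6 falls of 23, 5 and 6 adjusted over the list alone, with a median of 0.02 and a mean of -0.01 (adjusted p = 0.806; adjusted p = 0.913 with an estimated correlation), UTP20 higher (0.44 ± 0.0650) and BOP1 lower (-0.38 ± 0.0734). The rises numbered 1 without wild-type replicate 1 or 2 or knockout replicate 3 and 2 without knockout replicate 1, and the falls 3 without wild-type replicate 2 or knockout replicate 1. Of 13 cancer-testis genes PRAME (-0.76 ± 0.0680) and TKTL1 (-0.60 ± 0.0611) fell and PAGE1 rose (0.21 ± 0.0730), though PAGE1 did not pass when adjusted over the list alone and its adjusted p of 0.0488 became 0.0664 to 0.151 without wild-type replicate 1, 2 or 3 or knockout replicate 1 or 3. Without wild-type replicate 1, 2 other genes of the list rose. That list's median of 0.03 and mean of -0.06 differed in sign (adjusted p = 0.735; adjusted p = 0.906 with an estimated correlation).

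Markers of cells foreign to an epithelial line made up 3 lists, none of which passed camera. The rotation test fry called the immune (adjusted p = 0.00705) and fibroblast (adjusted p = 0.0121) lists lower. Of 12 fibroblast markers COL6A3 (0.65 ± 0.0677) and PDGFRB (0.23 ± 0.0572) rose and LUM fell, with a median of 0.04 and a mean of -0.21 (adjusted p = 0.877; adjusted p = 0.913 with an estimated correlation). Of 13 immune markers 0 rose, while LYZ, the lysosomal glycoprotein CD68 (-1.38 ± 0.0977) and the endotoxin coreceptor CD14 (-0.30 ± 0.0793) fell (median -0.08; adjusted p = 0.143; adjusted p = 0.472 with an estimated correlation), the last with an adjusted p of 0.0532 without knockout replicate 1. Without knockout replicate 3, 1 of them rose. Of 10 endothelial markers the junction gene ESAM rose (0.28 ± 0.0643) and the cadherin CDH5 fell (-0.79 ± 0.111), with a median of 0.09 and a mean of -0.01 (adjusted p = 0.741; adjusted p = 0.892 with an estimated correlation).

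Neighbouring genes changed together in 5 stretches found by a scan added after the data were seen, with chromosomes and gene order taken from GRCh38.p14. On chromosome 9, 62 of 85 genes from ACO1 to ENTREP1 rose and 3 fell (median 0.64), 18 of 27 from DMAC1 to C9orf72 fell and 1 rose (median -0.48), and 12 of 20 from SLC44A1 to KIAA1958 fell (median -0.33). On chromosome 8, 29 of 42 genes from PINX1 to SORBS3 fell and 1 rose (median -0.41), and on chromosome 3, 16 of 21 from MRPL3 to ARMC8 rose and 3 fell (median 0.40). The largest median of 21 consecutive genes was 0.79 in size, against a threshold of 0.35 from 9999 shuffled gene orders, none of which reached it (permutation p = 1e-04, the smallest they can give). The MRPL3 to ARMC8 and SLC44A1 to KIAA1958 stretches lay close to that threshold (largest medians 0.37 and 0.36 in size). Neither was found with windows of 11 genes, which gave 1 lower stretch on chromosome 4 instead (DCK to CDKL2, with CXCL8 among its genes). Windows of 41 genes gave 13 stretches, and the SLC44A1 to KIAA1958 stretch was not among them. Of the 66 genes at least 2-fold higher in knockout cells, 16 lay in the ACO1 to ENTREP1 stretch, and 11 of the 392 at least 2-fold lower lay in any of the 5.

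**Figure D3:**
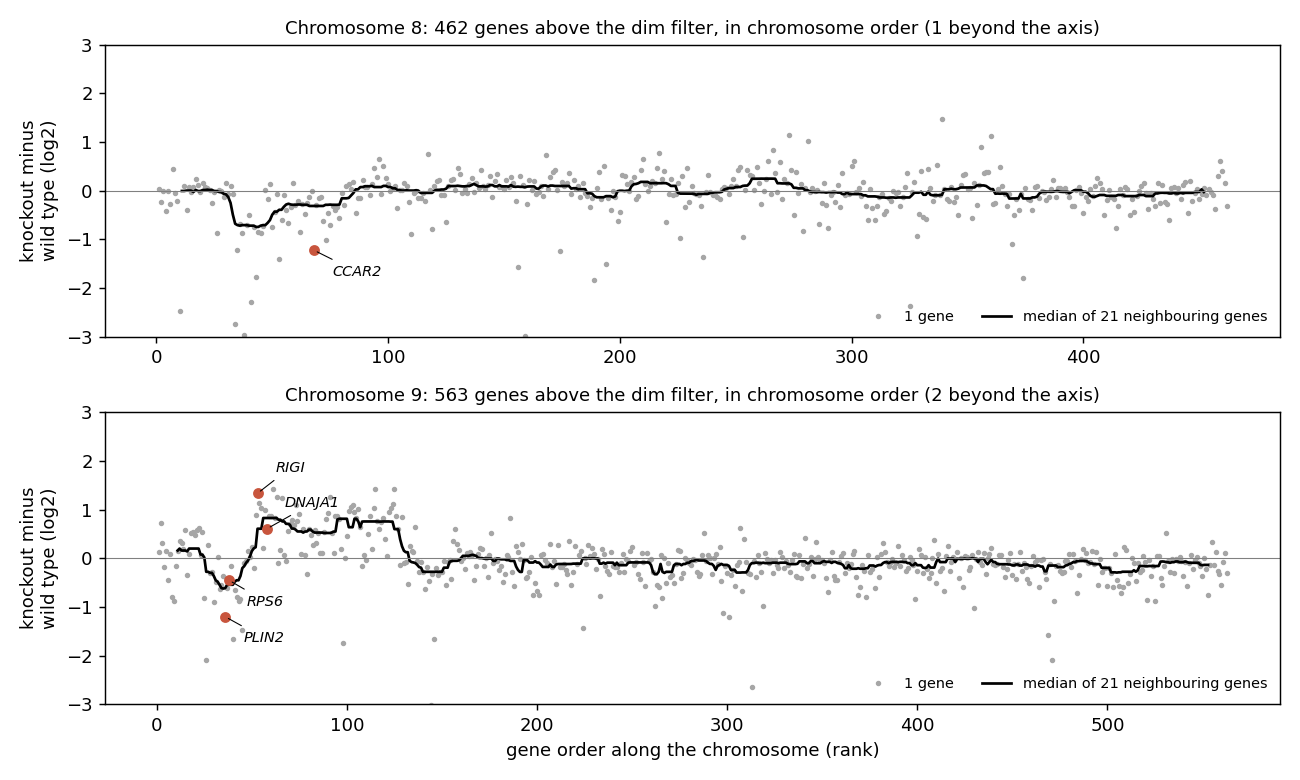
Log2 difference, knockout minus wild type (vertical axis), of genes above the dim filter in their order along chromosomes 8 and 9 (horizontal axis), with 1 point per gene and a line for the median of 21 neighbouring genes. The stretch from ACO1 to ENTREP1 lies above 0 with a median of 0.64, and those from PINX1 to SORBS3 and from DMAC1 to C9orf72 lie below 0, with medians of -0.41 and -0.48.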

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

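The tests in this part were chosen after the result was seen, except the counts over other splits of the arrays. The comparisons of genes used those with a single symbol. In a fit of every probe set on its own, adjusted over all 33297, 1647 of the 13837 probe sets with several symbols or none passed limma's adjusted p under 0.05, 844 of them higher and 803 lower in knockout cells. At least 2-fold higher were 22 of them, above the wild-type level, and 62 were at least 2-fold lower. The probe set with the lowest p among the rises, 8090416, is not listed in the annotation used, and it read 7.61 to 7.64 on the wild-type arrays and 9.78 to 9.99 on the knockout arrays, a log2 difference of 2.28. Lowest in p among all of them was a fall, of probe set 7997962, also not listed. It read 12.92 to 13.02 on the wild-type arrays and 8.11 to 8.24 on the knockout arrays, a difference of -4.82.

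Stretches of neighbouring genes on chromosomes 3, 8 and 9 moved together in knockout cells, on all 3 knockout arrays, where brighter genes of the ACO1 to ENTREP1 stretch had median log2 differences of 0.70 to 0.76. For the largest window, in the ACO1 to ENTREP1 stretch, a chance order of genes is argued against by permutation of the gene order (p = 1e-04, the smallest that 9999 shuffles can give), while the MRPL3 to ARMC8 and SLC44A1 to KIAA1958 stretches were not found with windows of 11 genes. A lesion at the CCAR2 site alone is argued against by the 4 of 5 stretches on chromosomes other than 8, although for the chromosome 8 stretch it stays open. A candidate explanation is a difference in copy number between the cultures. When stretches were found on every other gene, 19 of the 23 brighter genes in between moved in the stretch's direction (82.6%, exact 95% interval 61.2 to 95.05, which treats neighbours as independent). By stretch, 7 of 7 fell in PINX1 to SORBS3 and 12 of 16 rose in ACO1 to ENTREP1. The 7 lay between ZDHHC2 and DOK2, and the 16 between RIGI and UBE2R2 or between RUSC2 and PAX5. The other parts of these 2 stretches were not covered. Among all brighter genes scanned on the chromosomes 55.4% were higher. That share is a base for the rising stretch only, and the 12 of 16 were not tested against it. The scan on every other gene did not find the MRPL3 to ARMC8 and SLC44A1 to KIAA1958 stretches again. In the DMAC1 to C9orf72 stretch it found only the window at SCARNA8, which left 0 genes in between. For these 3 stretches a copy number difference cannot be told apart from other explanations. Regional regulation would move neighbours in the same way and no DNA was analysed here, so an effect of DBC1 loss on these regions, which was not tested, also stays open.

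CCAR2 fell more than most genes around it, as the 25th and 75th percentiles of its 40 nearest genes were -0.47 and -0.12. Of these 40, 1 (2.5%) fell as much. In the PINX1 to SORBS3 stretch, which ends shortly before CCAR2 and can share genes with that set, 5 of 42 (11.9%) did. Genes that were not targeted thus fell as far, so the share of the region in the fall of CCAR2 cannot be told apart.

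Falls made up 85.6% of the changes of at least 2-fold. The share of falls was at least 82% under the 3 other scalings, but these could not decide whether the centring between arrays is a cause. They left the median difference of all genes between 0.0259 and 0.0789, against 0.0325 in the main fit. Such moves are small beside the log2 cut of 1. The stretches of neighbouring genes are argued against as the whole cause, because without them the share of falls was 88.4%. A loss of fibroblasts or endothelial cells from the knockout culture is argued against, but only weakly, by their 7 and 4 markers above the dim level. The median log2 differences of these were 0.0493 and 0.0864 (COL1A1, the brightest fibroblast marker at 8.63, differed by -0.10). Over each whole list 1 marker fell (LUM and CDH5), while 2 fibroblast markers and 1 endothelial marker rose. The rotation test fry called the fibroblast list lower (adjusted p = 0.0121). By marker genes alone, immune cells lost from the knockout culture cannot be told apart from a change within SW480 cells. Of the 6 immune markers above the dim level only 3 fell (CD68, LYZ and CD14), 1 of which is also a secretory marker. The labels name SW480, an established line, and no other cells. An effect of DBC1 loss, or of the history of the cells from which the knockout was grown, may account for the imbalance, and neither was tested.

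Of the 10 ways to split the 6 arrays into 3 and 3, 1 gave as many genes as the real one, namely itself, with 7229 genes, 458 genes of at least 2-fold and 12 lists. The highest counts in the others were 0 genes, 0 genes of at least 2-fold and 5 lists, with at most 676 genes at an unadjusted p under 0.05 by limma. The splits are too few for a share under 0.05. Each of the others mixes the genotypes, which puts the genotype difference into the spread within its groups and lowers its count of genes.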

How the results depend on the processing

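The alternatives that left out the stretches of neighbouring genes or changed the scan's window were chosen after the result was seen. The count of genes past the threshold ranged from 5996 without wild-type replicate 2 to 8262 with array weights, and that of at least 2-fold changes from 391 without dim genes to 472 without wild-type replicate 2. CCAR2 lay between -1.27 and -1.15 throughout, and over the combinations of named gene and setting, direction and side of the threshold held in 2380, the call was lost in 37 and the sign turned in 3. Most named genes were chosen for large changes or low p, so this stability does not describe all calls. Of the 7229 genes called in the main fit, 5837 kept their call without wild-type replicate 2, the fewest of the settings compared. Without the stretches of neighbouring genes 7063 genes passed. The same-numbered arrays paired at most in part. Their deviations correlated by 0.26 for number 1 and 0.21 for number 3, the highest of all pairs, but by -0.04 for number 2. Not every array correlated best with its own number. The fit with the replicate number as a block called 7435 genes.

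The number of gene lists past the threshold was 0 with an estimated correlation and 24 by fry. CTNNB1 turned to 0.0106 when quantile-normalized again and to 0.0239 when centred, and LEF1 ranged from -0.00927 to 0.0725 over the replicates left out. Lists that turned under a setting that kept all arrays, uncalled except where given, were heat shock (adjusted p = 0.925 centred, 0.916 with array weights, 0.866 by fry), fibroblast markers (0.561 without dim genes), ribosome biogenesis (0.916 with array weights, 0.979 by fry), apoptosis (0.916 with array weights) and fatty acid genes (0.00933 by fry, a call). With replicates left out, 6 lists turned in at least 1 case, none of them called. Their adjusted p ran from 0.815 to 0.983 for heat shock, 0.630 to 0.968 for ribosome biogenesis, 0.712 to 0.998 for apoptosis, 0.614 to 0.99 for fibroblast, 0.525 to 0.922 for cancer-testis and 0.611 to 0.998 for endothelial genes. Windows of 11 genes gave 5 stretches, 4 of them on chromosomes 8 or 9 and 1 on chromosome 4, and windows of 41 gave 13, on 9 chromosomes. Counts of list members that moved by over 1.5 times included the following. Centred on the median, rises numbered 6 for apoptosis, 6 for secretory, 5 for sirtuin, 3 for enterocyte, 3 for cancer-testis and 2 for endothelial genes, and falls 3 for sirtuin, 3 for ribosome biogenesis, 1 for cholesterol and 1 for DBC1 partner genes. Histone rises numbered 3 when quantile-normalized again and 2 at a common 75th percentile. With the trended robust prior, falls numbered 10 for ribosomal protein and 7 for NRF2 genes, and without dim genes 3 for stem cell markers and 0 for fibroblast markers, as the filter removed LUM. The cause of these changes was not tested. The arrays carry no detection calls, so signal over background limits genes near the floor.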

Other observations

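All tests in this part were chosen after the result was seen, and the genes were named after their values were seen. Semaphorins, secreted or membrane-bound guidance factors, were over-represented among the steepest falls. Of 19 measured, SEMA3A, SEMA3C (-3.34 ± 0.0701), SEMA6A (-1.67 ± 0.0901), SEMA3F (-1.63 ± 0.0798), SEMA4G (-1.23 ± 0.0861) and SEMA3E (-1.11 ± 0.0530) fell at least 2-fold (Fisher's exact test over 490 groups of genes sharing a symbol stem, adjusted p = 0.000941). These 6 genes lie on 4 chromosomes, but SEMA3A, SEMA3C and SEMA3E share chromosome 7 with SEMA3D, which fell too (-0.93 ± 0.107), and Fisher's test counts such genes as independent. Over all calls, 10 semaphorins fell and SEMA5A rose (0.20 ± 0.0520), and there the stem did not pass (adjusted p = 0.0817).

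CXC chemokines were the other stem past the threshold among the 2-fold falls, with 4 of 14 genes (Fisher's exact test, adjusted p = 0.0419). These were CXCL1 (-3.7 ± 0.0984), CXCL8 (-3.62 ± 0.0741), CXCL2 (-2.17 ± 0.107) and CXCL6 (-1.28 ± 0.0905), neighbours on chromosome 4 within a stretch, DCK to CDKL2, that was lower with windows of 11 genes, so they too are not independent. CXCL3 (-0.53 ± 0.0748), CXCL11 (-0.37 ± 0.119) and CXCL10 (-0.19 ± 0.0646), also on chromosome 4, fell by less than 2-fold. In wild-type cells CXCL11 (5.61) and CXCL10 (4.45) lay below the dim level of 6.86, so their falls may be background. CXCL14 on chromosome 5 (2.16 ± 0.0694) and CXCL16 on chromosome 17 (0.18 ± 0.0565) rose. Of 20 CC chemokines 8 fell, with CCL7 (-2.76 ± 0.117), CCL24 (-0.76 ± 0.0683), CCL5 (-0.66 ± 0.0648), CCL11 (-0.66 ± 0.0935), CCL1 (-0.53 ± 0.0806) and CCL26 (-0.34 ± 0.0846) besides CCL20 and CCL2, while CCL28 rose (0.74 ± 0.0668), and that stem did not pass. Over all calls, 8 of 11 genes of the MCM stem rose (adjusted p = 0.0297), MCM9 (0.47 ± 0.0509) and MCM8 (0.50 ± 0.0781) among them, 13 of 25 dual-specificity phosphatase genes fell (adjusted p = 0.0199), and all 8 variant U1 small nuclear RNA genes fell (adjusted p = 0.000539), whose near-identical sequences the probes could share. Of these RNA genes, RNVU1-3 (6.14 in wild-type cells) and RNVU1-17 (4.07) lay below the dim level. The other stems past the threshold over all calls were ZNF (145 of 494 genes), SLC (115 of 376), VPS (18 of 34), USP (23 of 52), CEP (18 of 37) and SUPT (6 of 7) among the rises and PLA (12 of 20) among the falls. No stem of the 490 passed among the 2-fold rises.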
